A study of Caenorhabditis elegans with 2 samples.

How the data were processed

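Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans L4 larvae carrying SAEG-2 tagged at its own locus with TY1, EGFP and 3xFLAG, a CRISPR insertion, per the labels. The larvae came from bleached, L1-starved populations and were collected at 48 h. Chromatin was sonicated to a size range of 200 to 800 bp and precipitated with an anti-GFP antibody, per the labels' protocols. The samples form 1 group of 2 biological replicates. No second condition and no control files were analysed here, so the comparisons are between peaks and the genome, between groups of genes, and between the replicates.

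The values used are peak lists on the ce11 assembly, the same sequence as WBcel235. Per the file list deposited with the series, the lists of the whole series were derived from the filtered alignments of both replicates, and each replicate's lists from its own alignments alone, in every case together with a further file whose kind is not stated. The lists of the whole series are therefore pooled, while each replicate's list was called separately. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of a peak is the authors' own, on a scale the sources do not state. It served only to describe, rank or filter peaks within its own list, and values from lists of different depth were set side by side without a test. The score of a peak in the deposited lists is capped at 1000 and follows the irreproducible discovery rate (IDR), which is lower where the ranking of a peak is more alike between the compared peak sets. The −log10 IDR values are in the deposited ranked lists and are capped at 5. Each thresholded list held only peaks with an IDR of 0.01 or lower in its ranked list, but not all of them: 58 such peaks were missing from the conservative list, 64 from the non-conservative list, 40 from that of replicate 1 and 34 from that of replicate 2. Apart from the further file named for every list, the thresholded lists, unlike the ranked ones, derive from an additional file of unstated kind, per the deposited file list. Why these peaks are missing is not given in the sources used here. The 2 ranked lists of the whole series also carry 16 columns of values per compared peak set, which were not used.

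Read totals are not part of these lists, so the depth of each replicate is unknown. Intervals on shares are 95% Wilson intervals, which cover counting error only. Neighbouring peaks and clustered genes are not independent, so exact tests on counts treat as independent what partly is not. Results were computed on the conservative list of the whole series, with each replicate's own thresholded list as its replicate value. Where a replicate is left out, the list of the other replicate alone took the place of the conservative list.

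Sharing between replicates required an overlap of at least 1 bp. It was compared with 1000 rotations, in which the peaks of each chromosome were moved together by a random distance, a two-sided test whose smallest possible p is 0.002. The same rotations gave the background for the share of summits in promoter windows and in 6 location classes, with Benjamini-Hochberg adjustment over the classes. A promoter window ran from 1000 bp upstream to 500 bp downstream of an annotated 5′ end of a protein-coding gene. The classes were assigned in the order coding exon, 5′ UTR, 3′ UTR, intron, noncoding exon and intergenic. Genes came from Ensembl release 115 for WBcel235, and sequence from the RefSeq copy of that assembly. All peaks lay within the chromosome lengths of that sequence. Peak counts per chromosome were compared with the share of the length by exact binomial tests, two-sided and adjusted over 6 chromosomes, and autosomal peaks in the outer 25% of the chromosome at either end with a share of 50% by the same test.

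A gene was called bound where a summit lay in the window of any of its annotated 5′ ends. In all, 32 lists of protein-coding genes fixed before the data were examined were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the 423 symbols written out in the lists, 412 were found as protein-coding genes, and other members were taken by the pattern of their symbol. tRNA, rRNA, snRNA, snoRNA and miRNA genes were compared in the same way with all other annotated genes, adjusted over these 5 classes.

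Words of 6 bases, with a word and its reverse complement taken as 1 (2080 in all), were compared between the 101 bp around each summit and flanks on both sides. The flanks began 200 bp from the summit and were set to hold 48 word positions each, so that centre and flanks both held 96, and so ended 252 bp from the summit. Peaks with the word at the centre alone were compared with peaks with it in the flanks alone by an exact binomial (McNemar) test, two-sided, adjusted over all words.

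Genes were named by a rule fixed before the data were examined. It took saeg-2, saeg-1, hda-2 and egl-4. It took the gene with the nearest annotated 5′ end for the 20 peaks of the conservative list with the highest signal values among those overlapping a thresholded peak in both replicates, with the other gene where a pair of windows held the summit. It took the 4 bound members with the highest signal value in each list past the threshold, and at most 2 such members in each other list. Words and noncoding RNA genes given as examples were chosen after their values were seen.

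The alternatives were the non-conservative list, the upper part of the conservative list by signal value, each replicate's list alone, peaks merged within 200 bp, a narrower promoter window (500 bp upstream to 250 bp downstream), the nearest gene within 2000 bp, rotation in place of Fisher's test, draws from the ranked peaks as background, wider centres, farther flanks, summits outside exons, summits within 100 bp of each other or a reciprocal overlap of 50% as the definition of sharing, and a wider definition of the chromosome arms. The planned stricter IDR of 0.01 was already the threshold of the lists, so the upper part by signal value was used. Windows matched for GC content, peaks over 500 bp from tRNA genes, the background without piRNA genes, rotation for the noncoding classes and the list with the missing peaks restored (for the peak count and the noncoding classes) were added after seeing the data.

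The test functions were tested on simulated data. With 1000 random peaks per run and 200 rotations, of which 250 were moved to annotated 5′ ends, the promoter test called 20 of 20 runs, and it called 3 of 20 runs without moved peaks. A list bound at 25.0% was called in 20 of 20 runs over 32 lists, with 1 call in 20 runs without such a list. Bound genes were drawn independently there, so neighbouring genes that share a peak were not simulated. A word written into 100 of 1000 centres was called in 20 of 20 runs over 2080 words, with 2 calls of any word in 20 runs without it. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.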

Results

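The data collected are ChIP-seq peaks of SAEG-2 in L4 larvae of Caenorhabditis elegans, 2 biological replicates of 1 group. SAEG-2 is a nuclear protein known to act with SAEG-1 and the histone deacetylase HDA-2 downstream of EGL-4, the cGMP-dependent protein kinase. The series asks where in the genome the tagged protein is found. The authors' conservative list, which rests on both replicates, held 1145 peaks, and the non-conservative list held 1307. The list of replicate 1 held 452 peaks and that of replicate 2 held 541, a ratio of 1.197. Peaks had a fixed width in most cases, 304 bp for 1079 of the conservative peaks. The depth of the libraries is unknown. Coordinates are those of ce11 (WBcel235).

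Both replicates marked the same places far more often than rotated peaks did. Of the peaks of replicate 1, 295 of 452 overlapped a peak of replicate 2 (65.3%, 95% Wilson interval 60.8 to 69.5), against 0.291% ± 0.265 (SD over rotations) when the peaks were rotated. Of the peaks of replicate 2, 302 of 541 overlapped a peak of replicate 1 (55.8%, 51.6 to 59.95), against 0.262% ± 0.230. The p of 0.002 in both cases is the smallest that the rotations can give. Sharing followed the signal value within each list. All 113 of the strongest peaks of replicate 1 were shared, while 38 of its 113 weakest were (33.6%, 25.6 to 42.7). In replicate 2, 128 of the 136 strongest peaks were shared (94.1%, 88.8 to 96.99) and 36 of the 135 weakest (26.7%, 19.9 to 34.7). Of the 1145 conservative peaks, 301 overlapped a thresholded peak in both replicates and 536 in neither. A peak in the ranked list of both was found for 1129. Those ranked lists held 43050 and 50310 peaks, and the share that rotated peaks would give was not computed. The last count is therefore no support for the 536 peaks.

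**Figure D1:**
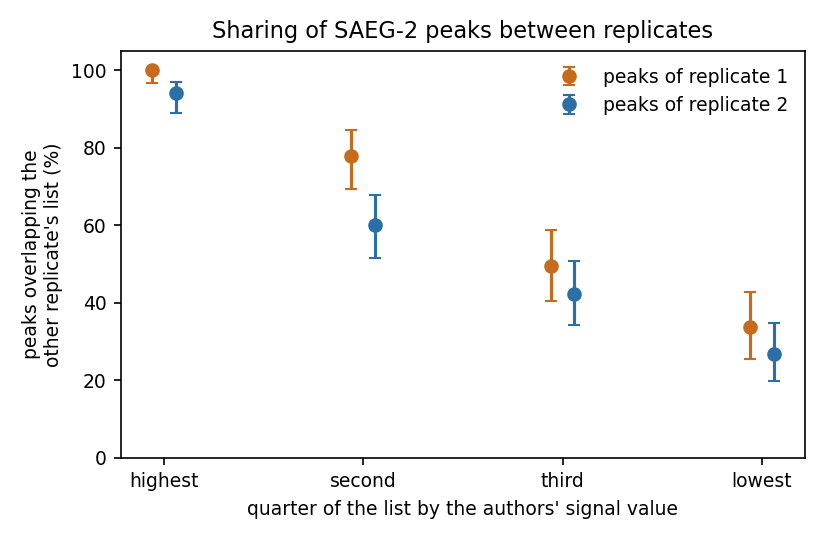
Share of each replicate's peaks (y axis, %) that overlap the other replicate's list, in 4 groups of near-equal size from the highest to the lowest signal value (x axis). Points are shares and bars 95% Wilson intervals. Sharing falls from 100% to 33.6% in replicate 1 and from 94.1% to 26.7% in replicate 2.

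Of the 10 highest signal values in the ranked list, 5 belong to peaks missing from the conservative list, which are described below. Among the conservative peaks the strongest lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit. It spanned III 3867464 to 3867681, intergenic, with its summit 277 bp upstream of the 5′ end, and its signal value was 589 in the conservative list, 267 in replicate 1 and 328 in replicate 2. The 41 bp around its summit (III 3867557 to 3867597) read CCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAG. The next lay between F44E5.4 and F44E5.5, a divergent pair of heat-inducible genes of the HSP70 family (II 11759326 to 11759635, signal value 540). Peaks between tasp-1 and K01G5.10 (III 10759117 to 10759362, 485) and in the windows of tag-340 and nhl-2 (III 4899820 to 4900044, 468) followed. The summit at tag-340 lay in an exon of a noncoding RNA gene. Others of the 20 strongest peaks found in both replicates lay in the windows of K08F11.1 (430), Y17G9B.5 and rpl-20 (360), cbp-1 (348), which encodes the worm homologue of the p300/CBP acetyltransferases, rpl-15 and K11H12.8 (346), nspc-17 (343) and rpa-2 (335). Of these 20 peaks 11 lay in a promoter window, and 7 lay over 2000 bp from any coding 5′ end. The latter were nearest to cmd-1, which encodes calmodulin (4771 bp, 464), W02H3.3 (4018 bp, 389), K02D3.1 (6057 bp, 368), the peroxidasin gene pxn-1 (5682 bp, 359), cest-16 (3399 bp, 356), nhr-88 (2501 bp, 334) and bcat-1 (5003 bp, 331). The peaks nearest to F20B6.9 (1796 bp, 385), F55C5.17 (1100 bp, 371) and ZK1248.17 (682 bp, 371) lay closer, the last in the window of H41C03.3 and 6 bp from the 5′ end of sls-2.1, a gene of the SL2 spliced leader RNA.

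Of the genes known to act with SAEG-2, saeg-1 held peaks and the others did not. The gene saeg-1 (V 10852518 to 10865699) had an intronic peak at V 10858498 to 10858641 with a signal value of 302 in the conservative list, 131 in replicate 1 and 175 in replicate 2, thresholded in both replicates. Its summit lay 1190 bp downstream of the nearest annotated 5′ end, outside the promoter window, and the 41 bp around it read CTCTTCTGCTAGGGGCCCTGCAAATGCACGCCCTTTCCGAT. A further peak (V 10855373 to 10855676, signal value 101) lay 284 bp upstream of an internal 5′ end of saeg-1 and thus in its window, but was in neither replicate's thresholded list. The window of saeg-1 was bound in the list of replicate 2 through another peak, 746 bp upstream of the gene's outermost 5′ end (V 10866305 to 10866584, signal value 65.1), which the non-conservative list also holds (90.6) and the conservative list and that of replicate 1 do not. The windows of saeg-2 itself, hda-2 and egl-4 held no conservative peak, the nearest summits lying 86406, 5627 and 16687 bp from their 5′ ends.

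**Figure D2:**
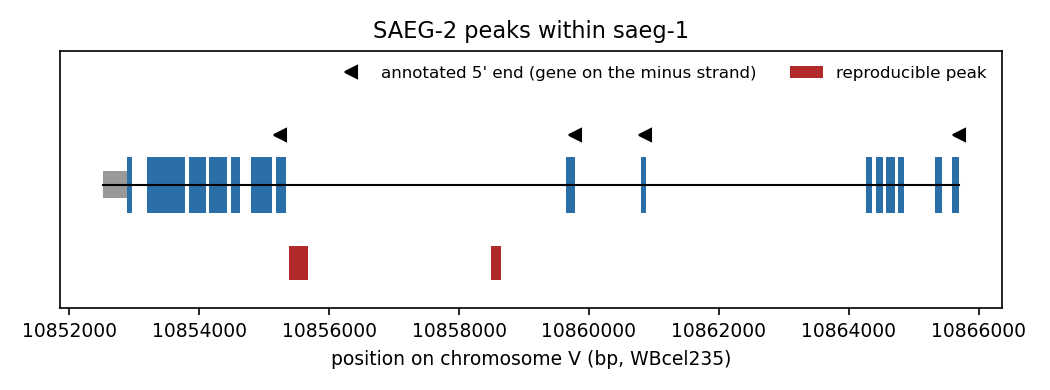
Map of saeg-1 on chromosome V (x axis, bp in WBcel235), with exons in grey, coding exons in blue, annotated 5′ ends as arrowheads and conservative peaks in red. The peak with a signal value of 302 lies in an intron, and the other lies 284 bp upstream of an internal 5′ end.

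Peaks gathered at promoters and in intergenic sequence and were sparse in coding exons. Of the 1145 summits, 536 lay in a coding promoter window (46.8%, 95% Wilson interval 43.9 to 49.7), against 31.4% ± 1.44 (SD over rotations) for rotated peaks (permutation p = 0.002, the smallest possible). The share was 50.7% in replicate 1 and 50.3% in replicate 2. Intergenic summits made up 48.1% (rotated 34.7%) and noncoding exons 11.4% (rotated 2.65%). Introns held 25.6% (rotated 33.4%), coding exons 10.3% (rotated 24.4%), 5′ UTRs 2.79% (rotated 1.42%) and 3′ UTRs 1.75% (rotated 3.399%). All 6 classes differed from the rotated peaks, each with an adjusted permutation p of 0.002. Coding exons held 4.42% in the list of replicate 1 and 4.81% in that of replicate 2, and 3′ UTRs 0.664% and 2.77%. In the replicates' own lists the 5′ UTR share did not pass (permutation, adjusted p = 0.132 in replicate 1 and 0.151 in replicate 2), nor did the 3′ UTR share in replicate 2 (adjusted p = 0.543). The median summit lay 884 bp from the nearest coding 5′ end.

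Genes of protein synthesis, chaperones and respiration were bound above the other protein-coding genes. Of 19973 protein-coding genes 619 were bound (3.10%). Among cytosolic ribosomal protein genes 21 of 82 were bound (25.6%, 95% Wilson interval 17.4 to 36.0; Fisher's exact test, adjusted p = 1.48e-12), 12 in replicate 1 and 14 in replicate 2. The strongest were rpl-3, rpl-20, rpl-15 and rpl-7A, the last with a signal value of 280, 54 bp upstream. With the nearest gene alone the share was 15.9% (exact adjusted p = 9.96e-05). Among heat shock protein and chaperone genes 15 of 60 were bound (25%, 15.8 to 37.2; exact adjusted p = 3.08e-09), 10 in replicate 1 and 12 in replicate 2, led by hsp-60 (286), which encodes the mitochondrial chaperonin, cct-8 (269) of the cytosolic chaperonin, hsp-3 (248), an HSP70 of the endoplasmic reticulum, and the J-domain gene dnj-13 (209). This call was lost when each peak was given to its nearest gene alone (6 genes, Fisher's exact test, adjusted p = 0.0700). Among oxidative phosphorylation genes 11 of 63 were bound (17.5%, 10.04 to 28.6; exact adjusted p = 2.64e-05), with cox-5A (289), cox-5B (146), cox-6A (124) and atp-1 (119.1) first; the shorter list of either replicate held 5 (7.94%), and the list passed in both. The share was 11.1% with the nearest gene alone and 9.52% with the narrower window or in the upper part by signal value, past the threshold in each. Translation factors had 7 of 39 bound (17.9%, 8.98 to 32.7; exact adjusted p = 0.00110), with eef-2 (202), iff-2 (193), eef-1G (155) and eef-1A.2 (138) first. The list of replicate 1 held 4 of these genes and that of replicate 2 held 5, past the threshold in both. No control precipitation was analysed here. For all 4 groups, binding of SAEG-2 therefore cannot be told apart from transcribed or open chromatin that any antibody may enrich.

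Histone deacetylase complex genes, the group SAEG-2 belongs to, had 4 of 20 members bound (95% Wilson interval of the share 8.07 to 41.6; Fisher's exact test, adjusted p = 0.0159). These were lin-53 (signal value 172, in both replicates), egl-27 (103, in replicate 2 alone), saeg-1 (101) and rcor-1 (78.1). The conservative peaks in the windows of saeg-1 and rcor-1 were in neither replicate's thresholded list. The list rests on few genes. It did not pass in the list of replicate 1, with 1 member bound (exact adjusted p = 0.687), and passed in that of replicate 2, with 3, saeg-1 among them through its upstream peak (exact adjusted p = 0.0213). Nor did it pass with the narrower promoter window (exact adjusted p = 0.187) or the nearest gene alone (adjusted p = 0.105), where lin-53 was not bound. Without a control precipitation, binding of SAEG-2 to this list too cannot be told apart from transcribed or open chromatin that any antibody may enrich.

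Chemoreceptor genes had 6 of 1319 bound (0.455%, 0.209 to 0.989; Fisher's exact test, adjusted p = 8.57e-11), with sre-23 (168), srh-70 (136), srh-2 (126) and srh-269 (105.3) the strongest. The list of replicate 1 held 5 bound chemoreceptor genes (0.379%) and that of replicate 2 held 2 (0.152%), below the other genes in both. The nearest gene alone gave 0.910% and the upper part by signal value 0.303%, again below. F-box, MATH and BTB family genes had 4 of 412 bound (0.971%, exact adjusted p = 0.0400), namely fbxb-58 (230), fbxb-85 (140), fbxb-72 (118) and fbxa-83 (90.6). C-type lectins and lysozymes had 2 of 298 bound (0.671%, exact adjusted p = 0.0405), spp-2 and spp-6, which share a peak (118.8). When peaks were rotated along the chromosomes, which keeps the clustering of genes, the chemoreceptors stayed below in this permutation test (adjusted p = 0.0213), while the F-box group (adjusted p = 0.655) and the lectin group (adjusted p = 0.650) did not pass. Rotated peaks also no longer gather at promoters, and bound 6.90 F-box and 4.49 lectin genes on average. A deficit is therefore harder to see in this test, and the loss of these calls cannot be laid to clustering alone. The lists of replicates 1 and 2 held 3 and 0 of the lectin genes and 3 and 4 of the F-box genes, and neither group passed in either. Both were also lost by the exact test in the upper part by signal value (adjusted p = 0.305 for F-box and 0.461 for lectins) and away from tRNA genes (0.0526 and 0.0559), and the lectins with the narrower window (0.0989).

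The remaining 24 lists did not pass, though 3 of them did in some alternatives. Of the 77 genes that the naming rule took and that were bound, 53 were bound in the list of replicate 1, 56 in that of replicate 2 and 48 with the narrower window. The rule took strong peaks, some of them for overlapping a peak in both replicates, so these counts do not measure how reproducible bound genes are. Against the 619 protein-coding genes bound in the conservative list, 295 were bound in the list of replicate 1 and 326 in that of replicate 2. Class B synthetic multivulva and DREAM genes came nearest, with 3 of 20 bound (Fisher's exact test, adjusted p = 0.0811), lin-54 (212) and lin-53 first. They passed by the same exact test in the upper part by signal value (adjusted p = 0.0260), the list of replicate 1 (0.0161) and the narrower window (0.0453). Heterochronic genes had 2 of 14 (14.3%), lin-42 (79.9) and lin-46 (70.98), but passed at 28.6% in the non-conservative list (exact adjusted p = 0.00656) and with the nearest gene alone (0.00964). Moulting genes had 2 of 27, myrf-1 (143) and lin-42. Proteasome genes had 3 of 33, with rpn-3 (135) and pbs-5 (96.9), and vacuolar ATPase genes 2 of 20, vha-12 (114) and vha-13 (96.7). Insulin signalling genes had 2 of 18, the 14-3-3 gene ftt-2 (217) and daf-16 (97.8), the FOXO transcription factor, and passed with the nearest gene alone (22.2%, exact adjusted p = 0.0175). Wnt signalling genes had 2 of 30, mom-1 (124.99) and mig-5 (120), and vulval Ras and Notch genes 2 of 32, sem-5 (107) and osm-11 (102). Germline genes had 2 of 43, ego-1 (137) and syp-4 (86.2), and cell cycle genes 2 of 47, cdc-48.1 (297) and pcn-1 (163). Histone genes had 3 of 72, with his-37 (248) and his-61 (88.8), and nuclear hormone receptors 10 of 274, with nhr-68 (261) and nhr-47 (137). In cGMP signalling, the pathway of EGL-4, 2 of 46 genes were bound, gcy-35 (126) and pde-4 (71.2). The gene pde-4, like vha-13 and col-185, was bound neither in the non-conservative list nor in either replicate's list, and gcy-35 was lost away from tRNA genes, with the narrower window and with the nearest gene alone. Cuticle collagens had 4 of 176, with col-185 (103.6) and col-85 (98.0), neuropeptides and insulins 2 of 143, ins-39 (154) and nlp-57 (85.3), and homeodomain factors 2 of 97, ceh-99 (136) and ceh-38 (91.7). Detoxification genes had 3 of 188, with gst-27 (93.8) and cyp-35C1 (81.5). The intestine list had 1 of 23, the GATA factor elt-2 (92.8), and body wall muscle 1 of 38, act-4 (72.3). None of 24 TGF-beta and body size genes, 34 neuronal, 32 pharyngeal, 75 sperm or 7 yolk genes was bound; the upper ends of the 95% intervals are 13.8%, 10.2%, 10.7%, 4.87% and 35.4%.

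**Figure D3:**
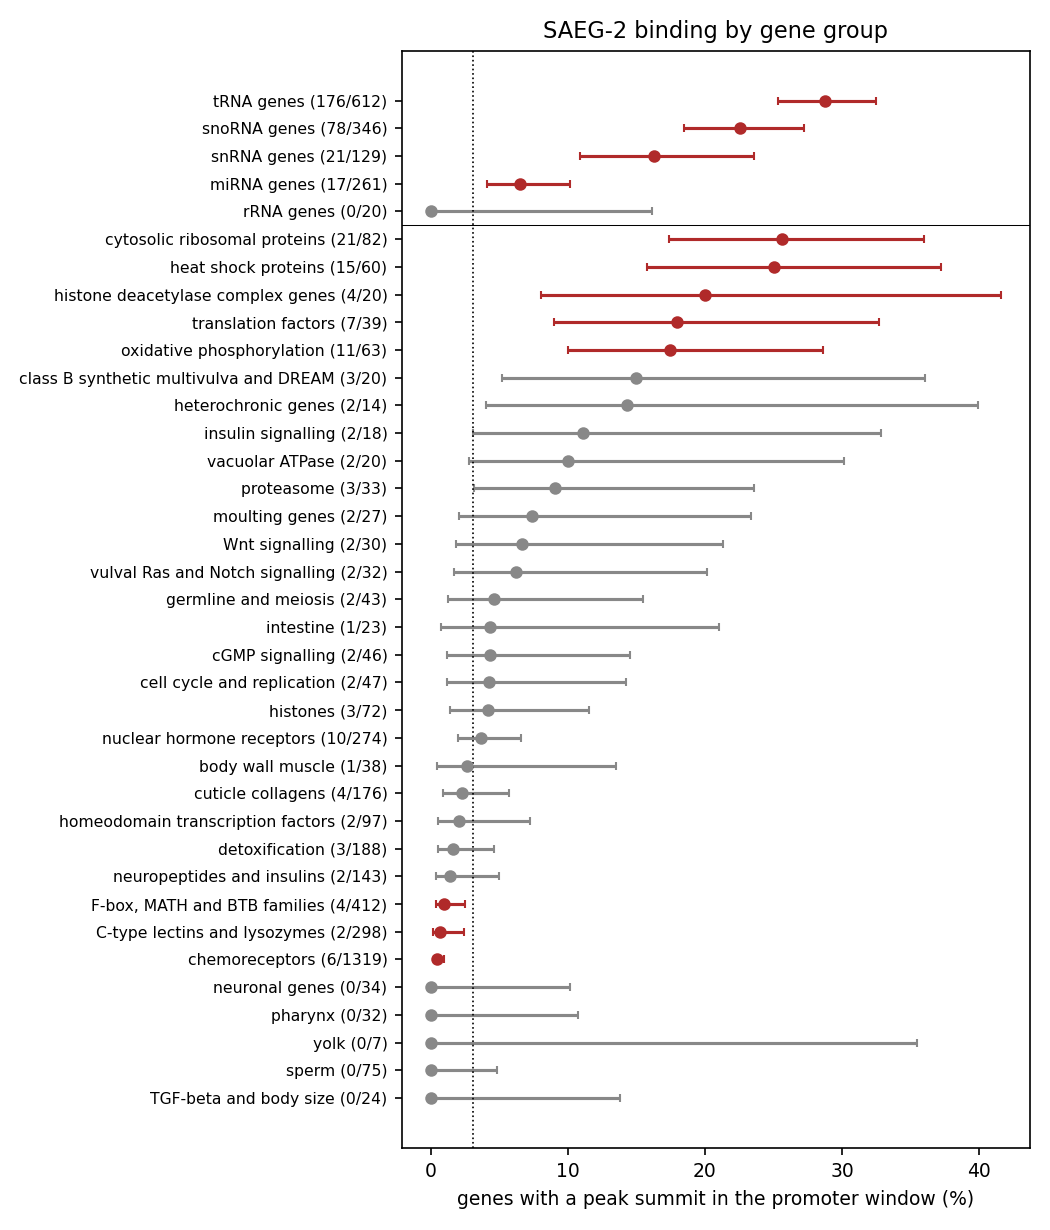
Share of the genes in each group with a conservative peak summit in the promoter window (x axis, %), with 95% Wilson intervals as bars and the counts beside each name. Noncoding RNA classes stand above the line, red marks groups past the adjusted threshold of 0.05, and the dotted line is the 3.10% of all protein-coding genes. tRNA genes reach 28.8% and ribosomal protein genes 25.6%.

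Genes of small noncoding RNAs were bound more often than other annotated genes. Of 612 tRNA genes 176 had a summit in their window (28.8%, 95% Wilson interval 25.3 to 32.5), against 2.67% of other genes (Fisher's exact test, adjusted p = 9.88e-120). By the same exact test snoRNA genes had 78 of 346 bound (22.5%, 18.5 to 27.2, adjusted p = 2.30e-44) and 21 snRNA genes were bound (16.3%, 10.9 to 23.6, adjusted p = 5.29e-10). miRNA genes had 17 of 261 bound (6.51%, 4.11 to 10.2, adjusted p = 0.00361). None of 20 rRNA genes was bound, with an upper end of the interval of 16.1%. The conservative list lacks 58 peaks with an IDR of 0.01 or lower in the ranked list, most of them in repeated sequence. With these restored, a choice made after seeing the data, 2 rRNA genes were bound (10%, against 3.03% of other genes, Fisher's exact test, adjusted p = 0.122). The replicates' own lists held 72 and 79 bound tRNA genes, 53 and 49 snoRNA genes, 11 and 9 snRNA genes and 5 and 9 miRNA genes. A window may also hold the peak of a neighbouring coding promoter. The snoRNA genes K11H12.12 and K11H12.13 were bound through the rpl-15 peak, and C06A1.9 through the cdc-48.1 peak. C51F7.3 and C51F7.4 were bound through a peak in no coding window. How many snoRNA, snRNA and miRNA genes were bound through coding promoters was not counted. Peaks at tRNA genes sat on the genes themselves: of 144 peaks in tRNA windows 83 had their summit inside a tRNA gene and 130 within 100 bp of one. The miRNA call was lost in the same exact test against annotated genes other than piRNA genes (adjusted p = 0.0764) and in the list of replicate 1 (adjusted p = 0.524). Genes that share a peak were counted separately, as were mir-54, mir-55, mir-55b and mir-56 on X. By rotation, tRNA, snRNA and snoRNA genes (permutation adjusted p = 0.00333 for each) and miRNA genes (0.005) stayed above. Rotated peaks no longer gather at promoters, so an excess is easier to see in this test.

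The X chromosome carried 269 of the 1145 peaks (23.5%, 95% Wilson interval 21.1 to 26.0), above its 17.7% of the length (exact binomial test, adjusted p = 3.97e-06). Chromosome V (15.98% of peaks, 20.9% of the length, exact adjusted p = 9.87e-05) and chromosome IV (13.4%, 17.4%, adjusted p = 4.23e-04) lay below their share. Chromosomes I, II and III did not pass (exact adjusted p = 0.836, 0.180 and 0.0975), but chromosome III lay above its 13.7% of the length in the non-conservative list (16.2%, exact adjusted p = 0.0170). The X share was 22.3% in replicate 1, where it did not pass (exact adjusted p = 0.0680), and 25.9% in replicate 2 (adjusted p = 1.17e-05). Nor did chromosomes IV and V pass in replicate 1 (exact adjusted p = 0.216 and 0.226), while both did in replicate 2. tRNA genes are unevenly placed: 276 of 612 lie on X. Among the 1005 peaks over 500 bp from any tRNA gene the X share was 19.6% (17.3 to 22.2, exact adjusted p = 0.139). On the autosomes, 359 of 876 peaks lay in the outer 25% at either end (40.98%, 37.8 to 44.3), below 50% (exact binomial p = 1.05e-07), and each replicate gave a like share, 40.7% and 41.1%.

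**Figure D4:**
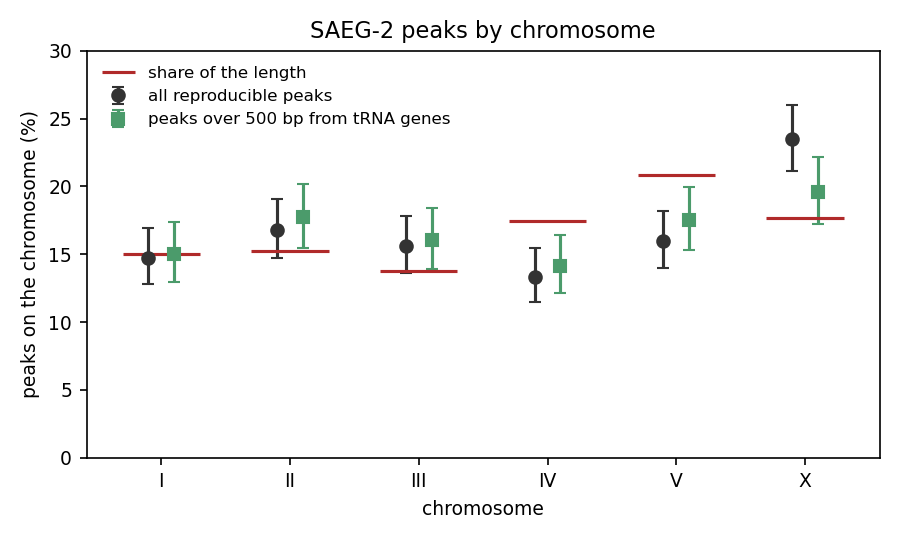
Share of peaks on each chromosome (y axis, %) for all 1145 conservative peaks (circles) and the 1005 over 500 bp from tRNA genes (squares), with 95% Wilson intervals, and each chromosome's share of the length (red lines). The X share is 23.5% for all peaks and 19.6% away from tRNA genes.

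Summits were richer in G and C than their flanks and held a set of recurring words. The GC content of the 101 bp around the summit was 47.5% ± 8.90 (SD over 1145 peaks), against 36.8% ± 8.46 in the flanks. Of 2080 words 459 were enriched at the summits and 305 in the flanks. Among the words enriched at summits the lowest p belonged to ACGCAG, found at 152 summits and in the flanks of 28 peaks (exact McNemar test, adjusted p = 1.89e-21). CGCAGA (136 and 21), AGACGC (131 and 35), CTCGCA (93 and 15) and CGTCTC (155 and 51) came next among these. Several of these overlap in the longer word GAGACGCAGA, present at 55 summits (4.80%, 95% Wilson interval 3.71 to 6.20) and in 4 flanks, with 27 of the 55 in a promoter window. The summit at tag-340 (III 4899906 to 4899946) reads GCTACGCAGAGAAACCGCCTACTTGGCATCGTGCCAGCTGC. This stretch holds ACGCAG and CGCAGA but not the longer word. Against windows of the same chromosome and GC content, chosen after seeing the data, 141 words were enriched, with the lowest p among them for ACGCAG (exact test, 152 summits and 47 windows, adjusted p = 3.31e-12), and GAGAGA also passed (201 and 83, adjusted p = 3.68e-11).

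**Figure D5:**
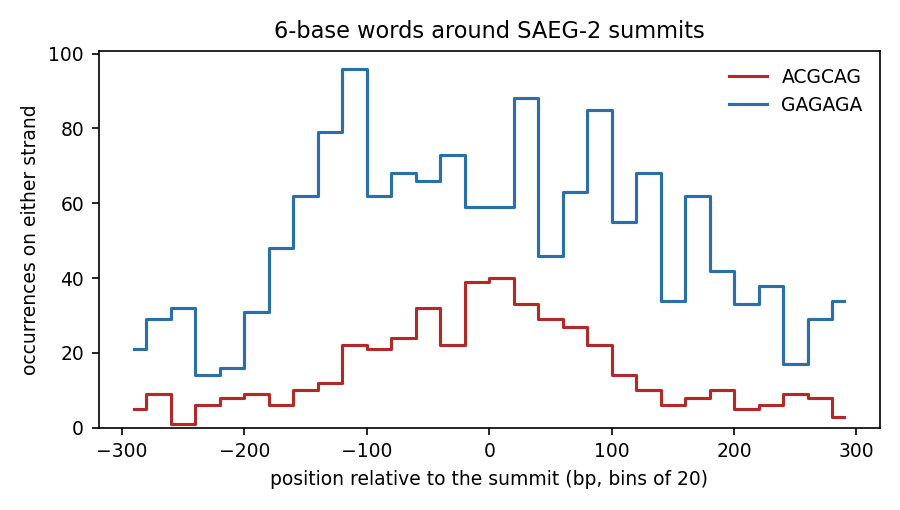
Occurrences on either strand (y axis) of the words ACGCAG and GAGAGA in bins of 20 bp around the 1145 summits (x axis, bp). ACGCAG rises to 40 occurrences in the bin from the summit to 20 bp beyond it, while GAGAGA is spread over a wider stretch.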

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

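The tests of candidate peaks on X, of X peaks away from both promoters and tRNA genes, and of other short RNA genes were chosen after their results were seen, and the peaks over 500 bp from tRNA genes and the GC-matched windows were alternatives added after seeing the data.

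A signal outside the main list drew attention: 58 peaks of the ranked list with an IDR of 0.01 or lower are missing from the conservative list. The strongest, at X 15810938 to 15811173 near a pseudogene, has a signal value of 2682, which is 4.56 times the highest in the conservative list, with 1294 in replicate 1 and 1518 in replicate 2. In 54 of the 58 (93.1%) at least 50% of the 32-base words occur elsewhere in the genome, against 73 of the 1145 kept peaks (6.38%). Per the deposited file list the thresholded lists, unlike the ranked ones, also derive from an additional file of unstated kind, apart from the further file named for every list. The missing peaks form 34 groups within 10 kb, and 1 lies at rrn-4.2, a 5S rRNA gene, and another near sls-1.1, a gene of the SL1 spliced leader RNA.

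The X chromosome carried 23.5% of the peaks. Neighbouring peaks counted separately are argued against, since merged loci gave 23.6% (95% Wilson interval 21.2 to 26.3), and so is a general excess of candidate peaks, since X held 18.2% of the ranked list. The placing of tRNA genes may account for part: the X share fell to 19.6% (17.3 to 22.2) away from them, an interval that holds the 17.7% of the length. Whether it is the whole cause cannot be told apart, because among peaks outside promoter windows and away from tRNA genes the X share was 23.05% (19.6 to 26.9) against 18.8% of that sequence, with an exact binomial p of 0.0188 that becomes 0.0752 when adjusted over the 4 locations compared. With 1 group, no biological explanation was tested.

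Peaks at tRNA genes have technical explanations of their own. Neighbouring coding promoters are argued against, as 2.78% of the 144 peaks in tRNA windows lay nearer to a bound coding 5′ end. Of the bound tRNA genes with identical copies, 98.7% (95.4 to 99.6) had an unbound one. Of the 43 groups of identical genes with a bound gene, 42 also held an unbound one. Any unbound copy sufficed for this, and copies of near-equal signal may fall on either side of the peak threshold. These counts therefore cannot decide whether reads were spread evenly over identical copies. Uneven sharing of reads between similar copies stays open: the bound share of tRNA genes without a repeated 32-base word was 0.308 times that of those with one, but only 22 genes lacked such a word (2 bound, against 174 of 590). Of the 140 peaks within 500 bp of a tRNA gene, 1 (0.714%) consisted mostly of repeated words, and 9 (6.43%) held none. Among all 1145 conservative peaks 6.38% consisted mostly of repeated words, and 70.3% held none. The median share of repeated words was 19.4% near tRNA genes and 0% over all peaks. A tRNA gene is shorter than the usual peak of 304 bp, so a repeated gene need not make a peak mostly repeated. The count of 1 therefore does not argue against shared reads. Transcribed or open chromatin that any antibody may enrich stays open too, since 2 of the 3 classes rRNA, snRNA and snoRNA were also bound above other genes. With the missing peaks restored, rRNA genes (2 of 20, 10%) lay above the 3.03% of other genes without passing (Fisher's exact test, adjusted p = 0.122). Neighbouring coding promoters were not tested for these classes, and no control precipitation was analysed here. With 1 group, no biological explanation was tested.

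The words at the summits could come from the higher GC content there. For ACGCAG this is argued against as the whole cause, since it was in 3.23 times as many summits as GC-matched windows, although the number of enriched words fell from 459 to 141 with that control. The sequence of tRNA genes is argued against as well, since away from them ACGCAG was in 5.83 times as many summits as flanks. A word recognised by SAEG-2 or by a factor that brings it there is a hypothesis these lists cannot test, as no other factor's peaks were analysed here.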

How the results depend on the processing

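The list with the missing peaks restored, the peaks over 500 bp from tRNA genes and the GC-matched windows were chosen after seeing the data. The sharing between replicates, the promoter share, the arm share and the number of lists past the threshold kept their call, or stayed within 1.5 times, in all alternatives run. The peak count was 572 for the upper part by signal value and 452 to 541 with a replicate left out, by construction, and 1203 with the missing peaks restored. The X share was 22.3% to 25.9% with a replicate left out and 19.6% away from tRNA genes; the cause was not tested with a replicate left out. Enriched words numbered 211 to 291 with a replicate left out, which leaves fewer peaks, 301 at summits outside exons and 141 against GC-matched windows; the cause was not tested for the first 2 of these.

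Lists and classes that passed the threshold in neither setting changed side of the other genes as follows, in % of genes bound. Left-out replicates gave 0 to 7.41 for moulting genes, 0 to 7.14 for heterochronic genes, 1.39 to 1.39 for histones, 0 to 5 for vacuolar ATPase, 0 to 4.35 for intestine, 1.09 to 1.46 for nuclear hormone receptors, 0 to 6.67 for Wnt signalling and 0 to 3.12 for vulval Ras and Notch signalling. The upper part by signal value gave 0 for heterochronic genes, 1.39 for histones, 0 for intestine and 1.09 for nuclear hormone receptors. The nearest gene alone gave 8.33 for TGF-beta and body size, 5.68 for cuticle collagens, 2.78 for histones, 2.33 for germline and meiosis, 5.26 for body wall muscle, 4.20 for neuropeptides and insulins, 3.33 for Wnt signalling and 4.26 for detoxification. The narrower window gave 2.17 for cGMP signalling and 0 for heterochronic genes and for vulval Ras and Notch signalling, peaks away from tRNA genes 2.17 for cGMP signalling, and the non-conservative list 8.33 for TGF-beta and body size. Rotation, which keeps the share, put cuticle collagens (2.27), body wall muscle (2.63) and detoxification (1.60) above the rotated peaks. These rotated peaks no longer gather at promoters. With the missing peaks restored, 10% of rRNA genes were bound.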

Other observations

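The groups of small RNA genes below were chosen after their values were seen. Among snRNA genes, those of the SL2 spliced leader, which is joined to the 5′ ends of downstream genes of operons, had 10 of 18 bound (55.6%, 95% Wilson interval 33.7 to 75.4), 6 in the list of replicate 1 and 4 in that of replicate 2. Other snRNA genes apart from spliced leaders had 11 of 99 (11.1%, 6.32 to 18.8). None of 12 SL1 genes was bound in the conservative list and 2 were with the peaks missing from it restored (16.7%, 4.70 to 44.8), while the SL2 count stayed at 10. The missing peak near sls-1.1 consisted mostly of repeated words (63.4%). The conservative list may therefore understate SL1 genes, and the contrast with SL2 genes was not tested. The summits at sls-2.1 (signal value 371), sls-2.2 (242) and sls-2.4 (234.6) lay 6, 11 and 21 bp from the 5′ end, the first upstream and the others downstream. Among snoRNA genes, C51F7.3 and C51F7.4 share the peak at V 12303528 to 12303745 (371), and ZK994.7 lies 8 bp from a summit (359) within an intron of pxn-1. A cluster of miRNA genes on X, with mir-54, mir-55 and mir-56, holds a peak at X 13145229 to 13145532 (169).

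Peaks fell into groups by location. Of the 1145 peaks, 110 lay within 500 bp of a tRNA gene and outside any coding promoter window, 59 lay in the windows of other small RNA genes alone, and 440 (38.4%) lay in none of these. The last group had a median signal value of 92.3, against 100 for those in coding promoter windows, and 22.95% of them overlapped a peak in both replicates, against 28.9%. tRNA genes were bound in 93 of 276 cases on X (33.7%) and 83 of 336 on the autosomes (24.7%), where the share ran from 12.8% on V and 18.3% on IV to 33.3% on II and 37.5% on III, above that of X. Within ribosomal protein genes, 11 of 51 of the large subunit and stalk and 10 of 31 of the small subunit were bound. Within the chaperone list the bound genes were 7 of 22 hsp genes, 5 of 29 dnj genes and 3 of 8 cct genes, among them the small heat shock genes hsp-16.2 and hsp-16.41.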
